A study of Homo sapiens with 12 samples.

How the data were processed

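The series holds RNA-seq of HCT116 and HCT15 colorectal carcinoma cells, each as control cells and as cells overexpressing RNF26, with 3 libraries in each of 4 groups. Per the labels' protocols, total RNA was extracted with TRIzol, poly(A) RNA was selected with oligo(dT) beads, libraries were made with a stranded kit, and sequencing was paired-end. Groups and replicate numbers were taken from the sample titles. The authors deposited 1 table of TPM (transcripts per 1000000), with 1 column per library and 2 decimals, and each column summed to about 1000000. Per the submitters' processing notes, fastp, HISAT2, StringTie and RSEM were used and the genome build was GRCh38; their versions, roles and order and the annotation release are not given in the sources used here. The table lists 63036 identifiers, 62703 Ensembl genes and 333 loci with names of the kind StringTie gives to assembled loci. TPM divides out sequencing depth, so the depth per library is unknown, no counting interval is given, and no count model was used. A gene's TPM also depends on the other genes of its library, since all share a fixed total. Whether the quantification used the strand of the reads is not given in the sources used here, so values of overlapping antisense genes, readthrough loci and near-identical paralogs, among them tubulin, histone, HLA and ribosomal protein genes, are uncertain.

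Gene names, positions, GC content and transcript length came from the GENCODE annotation and sequence of GRCh38, and 42300 identifiers were matched to a symbol by Ensembl gene number. The GC content and length of a gene were the medians over all its annotated transcripts. No pair of libraries held the same values, with at least 24770 genes differing in each pair, so no library was counted as a copy of another. Of the tested genes 15 had the same values in all libraries as another gene.

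Tests were run in R 4.3.3 with limma 3.58.1 on log2(TPM + 1), on which scale fold changes understate the change of low genes. The 15584 genes with TPM of 1 or more in at least 3 of the 12 libraries were tested in 1 fit with a mean per group (lmFit, contrasts.fit, eBayes with a mean-variance trend, 8 residual degrees of freedom and a prior of 3.09). Tests were two-sided, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The contrasts were RNF26 against control in each line, the difference of these effects (HCT15 minus HCT116), their mean, and HCT15 against HCT116 controls. The RNF26 level was also tested by an exact permutation test of the TPM values of each line. Calls of both lines were compared by the overlap expected of independent lists and a one-sided Fisher exact test.

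The comparisons, their limma and camera tests, the alternative settings given below, 38 gene lists and the rule for named genes were chosen before the data were examined. Lists with at least 3 tested genes, 36 in number, were tested with camera with a preset correlation of 0.01, adjusted over the lists of each contrast, and tested again with an estimated correlation and with fry. Members were also adjusted over the list alone. The range given beside the adjusted p of a list covers the settings run with the preset correlation, and leaves out fry and the estimated correlation. The lists hold Wnt targets and components, cell cycle, epithelial and mesenchymal genes, stress, immune and metabolic pathways, RNF26 partners and neighbours, and markers of cells that the cultures should not hold. Lists of immediate early, mitochondrial, ribosomal protein and replication-dependent histone genes also read handling and RNA quality.

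Named genes were RNF26 and, for each line, the 10 largest rises and 10 largest falls among called genes with a mean TPM of 5 or more in the higher group, no overlap between the arms and a gene symbol that is not a clone, long intergenic RNA, antisense or pseudogene name. Of each described list up to 4 members with the smallest p in the contrast described were named. For the difference between lines the 10 genes with the smallest p under the same level rule were named, for the mean effect the 5 rises and 5 falls with the smallest p and the same sign in both lines, and for the control lines the 5 largest changes each way. Genes named outside this rule are said to be. Some genes that the rule selects are not reported here.

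Each result was recomputed with a pseudocount of 0.1 or 5, with no filter on low values or a filter of 5 TPM, with median-ratio scaling over 7524 genes of 5 TPM or more in every library, with quantile normalization, with a separate fit of each line, with eBayes without a trend or with robust estimation, with the replicate number as a block, and without each library in turn. Settings and tests added after the data were seen were a correction for GC content and transcript length, by a spline with 5 degrees of freedom per library over the 95.3% of tested genes with both values, the removal of mitochondrial and ribosomal protein genes before rescaling the rest to 1000000, and the list tests of the control lines.

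The fit was tested on simulated data in which known fold changes were put into 67 genes at 1.5 fold, 67 at 2 fold and 66 at 4 fold among 15584 genes. The changed genes were drawn from those with a mean log2(TPM + 1) in the line above the value for 5 TPM. The shares recovered therefore do not cover lower genes. Noise was normal and independent between genes, with no GC trend or shift of scale, unlike what real libraries may hold. Each gene had 1 SD, pooled over all 12 libraries, in the simulations of both lines. The shares recovered therefore do not compare the lines, and a wider spread in 1 group is not covered. In the simulation of HCT116 the fit called 71.6% of the 1.5-fold and 95.5% of the 2-fold changes, with 8 false calls. In that of HCT15 it called 52.2% and 95.5%, with 7 false calls. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.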

Results

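Messenger RNA was profiled in 12 libraries from HCT116 and HCT15, human colorectal carcinoma lines. HCT116 carries a mutant beta-catenin gene and HCT15 a mutant APC gene, so the Wnt pathway is altered in both. Each line was present as control cells and as cells overexpressing RNF26, an E3 ubiquitin ligase of the endoplasmic reticulum membrane, with 3 libraries in each of the 4 groups. The series title ties RNF26 to proliferation, metastasis and the Wnt pathway, and the comparisons ask which mRNAs differ with RNF26 in each line. Between 13582 and 14135 genes reached a TPM (transcripts per 1000000) of 1 or more in a library. TPM keeps no sequencing depth, so the depth behind each value is unknown. Correlations of log2 values between libraries were 0.969 to 0.979 within the HCT15 controls and 0.981 to 0.988 within the other groups. They were 0.983 to 0.986 between the arms of HCT116, 0.958 to 0.974 between the arms of HCT15, and 0.842 to 0.861 between lines. The SD of deviations from the group mean averaged 0.277 in HCT15 controls and 0.213 to 0.230 in the other groups. The fit shares 1 spread per gene over the groups, so it may understate the spread of HCT15 controls. The labels do not say that replicates were separate cultures, so p-values measure only the spread between these libraries, which may be technical.

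RNF26 mRNA was higher in the overexpressing libraries of both lines. In HCT116 it went from 16.8 ± 1.44 to 296 ± 39.4 TPM (SD, n = 3 each), a ratio of 17.6, and in HCT15 from 27.0 ± 0.762 to 54.2 ± 0.562 TPM (SD, n = 3 each), a ratio of 2.01. The log2 fold changes were 4.05 (SE 0.0915, limma with Benjamini-Hochberg adjusted p = 1.21e-09) in HCT116 and 0.98 (SE 0.0915, adjusted p = 4.97e-05) in HCT15. The effects differed between lines by -3.07 (log2, HCT15 minus HCT116, limma adjusted p = 1.14e-06). All 3 RNF26 libraries lay above all 3 controls in each line, which gave p = 0.1 in a two-sided exact permutation test, the smallest p that 3 against 3 allows. RNF26 (ENSG00000173456) lies on chromosome 11 of GRCh38, plus strand, from 119334527 to 119337313, as 1 exon with coding sequence from 119335123 to 119336421 and untranslated sequence on either side. TPM per gene does not separate mRNA of an introduced copy from that of the gene itself.

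**Figure D1:**
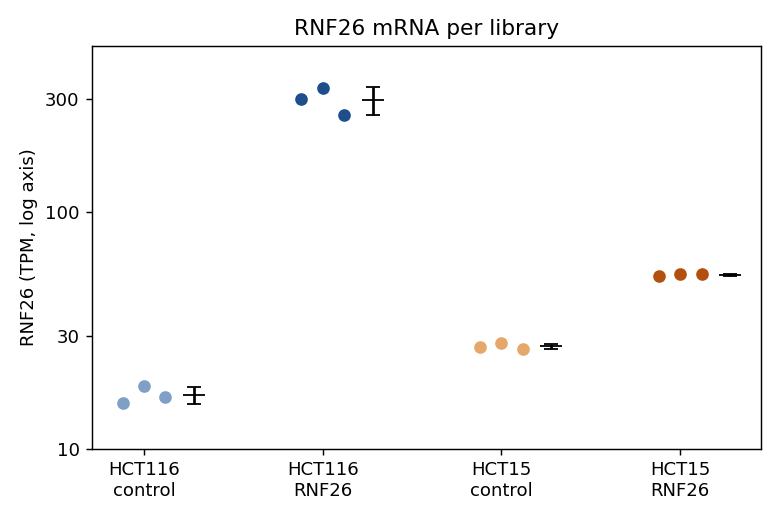
RNF26 mRNA (TPM, log axis) in each of the 12 libraries by group, with the mean and SD of each group of 3 beside the points. The HCT116 RNF26 libraries lie between 255 and 334 TPM and the HCT15 RNF26 libraries between 53.5 and 54.6 TPM, above the controls of their line.

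In HCT116, RNF26 was the single gene of 15584 tested that passed between the arms (limma, adjusted p under 0.05). MYC and AXIN2, Wnt targets named here after their values were seen, averaged 144 and 3.68 TPM in control and 144 and 3.80 TPM in RNF26 libraries. MYC encodes a transcription factor that drives cell growth, and AXIN2 a scaffold that feeds back on Wnt signalling. Of 31 tested Wnt targets, limma called 0, also adjusted over the list alone, and 1 had an unadjusted p under 0.05. That gene was JUN, with a log2 fold change of -0.29 (SE 0.125, unadjusted p = 0.0396), followed by NOTUM (-0.31), RNF43 (-0.19) and NKD2 (-0.27). Relative to all genes the list had a median of -0.00225 and a camera adjusted p of 0.631 (adjusted p = 0.956 with an estimated correlation). Over all genes 657 had an unadjusted p under 0.05, where 779 are expected by chance. RNF26 and control libraries did not overlap for 12.8% of genes, where chance gives 10%. The number of genes called was 11 with no filter on low values and 3 in a fit of HCT116 alone. It was 2 without HCT116 control replicate 1, 2 or 3 or HCT15 RNF26 replicate 3, and 3 without HCT15 control replicate 2.

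Some gene lists shifted slightly in HCT116 by camera, with no member called by limma over all genes. Genes of G2 phase and mitosis were higher, with 37 of 44 members above 0 and a median 0.05 above that of all genes (camera adjusted p = 0.0196, and adjusted p = 0.924 with an estimated correlation). CDK1, the kinase that drives entry into mitosis, averaged 136 ± 5.80 and 148 ± 6.55 TPM in control and RNF26 libraries, and the mitotic kinase AURKA 66.4 ± 2.44 and 71.1 ± 1.97 TPM (SD, n = 3 each). Interferon-stimulated genes were lower (-0.07, camera adjusted p = 0.0196, and adjusted p = 0.562 with an estimated correlation). So were genes of hypoxia and glycolysis (-0.06, camera adjusted p = 0.0230, and adjusted p = 0.789 with an estimated correlation) and p53 targets (-0.04, camera adjusted p = 0.0341, and adjusted p = 0.789 with an estimated correlation). Adjusted over the list alone, limma called 1 interferon-stimulated gene, DHX58, at 1.11 and 0.483 TPM, and 1 glycolytic gene, the aldolase ALDOC, at 35.1 and 25.3 TPM. It called 0 in the G2/M and p53 lists, where 0 and 1 genes had an unadjusted p under 0.05. Among p53 targets, GDF15 averaged 60.1 and 47.7 TPM and CDKN1A 144 and 130.4 TPM. In the mesenchymal list, which was not called (median -0.05, camera adjusted p = 0.0898, and adjusted p = 0.789 with an estimated correlation), limma called 2 genes adjusted over the list alone, the actin gene ACTA2 at 2.15 and 1.31 TPM and the actin-binding gene TAGLN at 2.51 and 1.24 TPM. The G2/M call ended without control replicate 1 (adjusted p = 0.0762) or RNF26 replicate 1 (0.0875) or 3 (0.0513) and after a correction for GC content and length (0.0906, range over the settings with the preset correlation 0.00304 to 0.0906), and the interferon call without control replicate 3 (0.0797) or RNF26 replicate 2 (0.0580, range 0.00446 to 0.0797). The hypoxia call ended without control replicate 1 (0.127) or 3 (0.0572) or RNF26 replicate 3 (0.0513) and after that correction (0.0513, range 0.00675 to 0.127), and the p53 call without control replicate 2 (0.117) or 3 (0.113) or RNF26 replicate 3 (0.151, range 0.0154 to 0.151).

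In HCT15, 5697 of 15584 genes differed between RNF26 and control libraries (limma, adjusted p under 0.05), 840 higher and 4857 lower. Among abundant mRNAs, the alpha-tubulin gene TUBA1B fell from 2251 ± 140.1 to 1112 ± 53.5 TPM and HSPB1, a small heat shock protein, from 1002 ± 134 to 305 ± 51.0 TPM (SD, n = 3 each). LCN2, which encodes the iron carrier lipocalin, rose from 349 ± 41.0 to 940.2 ± 3.01 TPM. The log2 fold change was 1 or more either way for 302 genes, 74 higher and 228 lower, and for 520 without HCT15 control replicate 2, 630 with a pseudocount of 0.1 and 81 with 5. RNF26 and control libraries did not overlap for 43.1% of genes, where chance gives 10%. Without HCT15 control replicate 3, which stood apart in its mitochondrial and ribosomal protein share, 653 higher and 4485 lower genes were called. In a fit of HCT15 alone it was 374 higher and 3528 lower. The balance of rises and falls moved with the scaling. It was 2242 higher and 2600 lower with median-ratio scaling, 2275 higher and 2521 lower with quantile normalization, 1397 higher and 3502 lower with mitochondrial and ribosomal protein genes left out, and 1767 higher and 2406 lower after a correction for GC content and length. The median log2 fold change of all genes was -0.17 as deposited and 0, -0.00216, -0.0826 and -0.0121 under these settings, in this order. List medians are therefore given relative to the median of all tested genes.

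**Figure D2:**
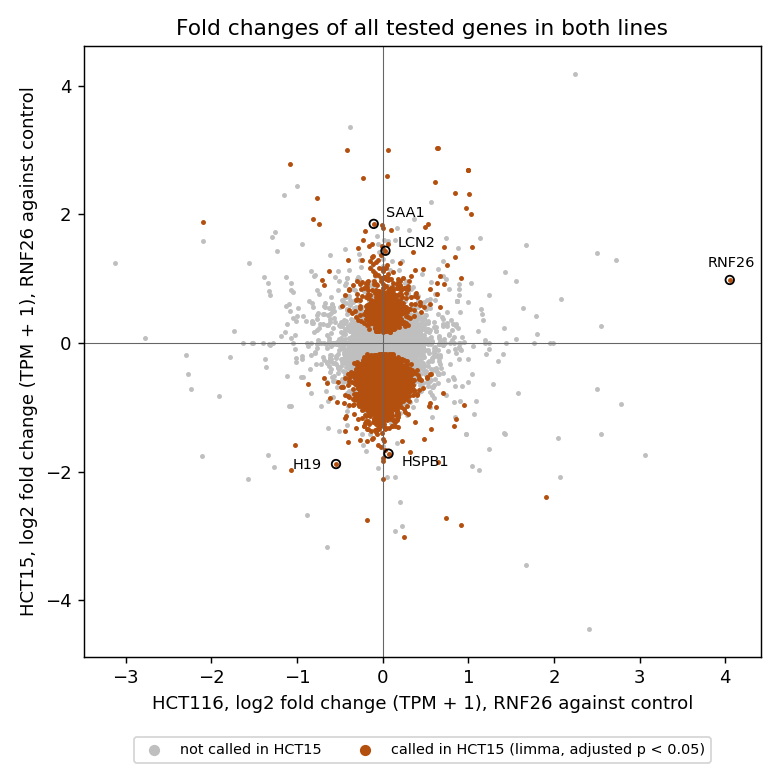
Log2 fold change (TPM + 1) of each tested gene in HCT116 (horizontal) against HCT15 (vertical), RNF26 against control. Colour marks genes called in HCT15 (limma, adjusted p under 0.05) and circles mark RNF26, LCN2, SAA1, HSPB1 and H19. The 5697 coloured points spread along the HCT15 axis, and RNF26 lies apart at 4.05 in HCT116 and 0.98 in HCT15.

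The largest falls in HCT15 lay in several functions. H19, an imprinted long noncoding RNA, fell by 1.88 (log2, SE 0.286, limma adjusted p = 5.64e-04), from 56.4 ± 15.0 to 14.3 ± 1.79 TPM (SD, n = 3 each). VIL1, the microvillus protein villin of intestinal epithelium, fell by 1.59 (SE 0.160), from 81.7 ± 21.1 to 25.8 ± 0.526 TPM. HSPB1 (-1.72), the phosphatase gene DUSP8 (-1.62), MYADM (-1.53), the circadian repressor gene NR1D1 (-1.51) and the kinase scaffold gene AKAP12 (-1.49) fell as well. SRP68, a subunit of the signal recognition particle, fell by 1.66 (SE 0.461, limma adjusted p = 0.0157) from a control mean with a wide spread, 181 ± 147 TPM, and MAP3K9, a kinase gene, fell by 1.49 (SE 0.451, adjusted p = 0.0235). The SRP68 call ended with no filter on low values (adjusted p = 0.0517) and in a fit of HCT15 alone (0.119; range over all settings 1.28e-04 to 0.119). The MAP3K9 call ended with no filter (0.0717), with quantile normalization (0.0527), after the GC and length correction (0.104), and without HCT15 control replicate 2 (0.0706) or 3 (0.0685) or RNF26 replicate 1 (0.0835) or 3 (0.0716; range 0.00865 to 0.104).

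The largest rises in HCT15 included SAA1, an acute-phase protein, which rose by 1.85 (log2, SE 0.228, limma adjusted p = 1.74e-04), from 15.7 ± 6.09 to 57.1 ± 10.9 TPM (SD, n = 3 each). NIBAN1, a stress-responsive gene, rose by 1.53 (SE 0.141), from 5.29 ± 0.967 to 17.2 ± 2.73 TPM, and LCN2 by 1.43 (SE 0.185). CTNNA2, an alpha-catenin gene, was listed at 0 in the control libraries and averaged 7.18 ± 5.02 TPM with RNF26, a wide spread (SD, n = 3, limma adjusted p = 0.00255). In HCT116 CTNNA2 averaged 1.75 ± 1.58 and 0.12 ± 0.208 TPM in control and RNF26 libraries. NMBR, the neuromedin B receptor, rose by 1.92, TEKTIP1 by 1.33 and CLPSL2 by 1.29. RNVU1-25, a variant U1 small nuclear RNA, rose by 3.03 with a wide spread, from 4.10 ± 7.11 to 19.6 ± 9.61 TPM. RPL36A-HNRNPH2 (2.60) and NEDD8-MDP1 (1.29) are readthrough loci that share exons with their neighbours, so their values are uncertain. In a fit of HCT15 alone the calls of NMBR (limma adjusted p = 0.0588), RPL36A-HNRNPH2 (0.0576), CLPSL2 (0.0676), NEDD8-MDP1 (0.0627) and RNVU1-25 (0.102) ended. Without HCT15 control replicate 3 those of RNVU1-25 (0.0743), TEKTIP1 (0.0790) and NEDD8-MDP1 (0.128) ended. Calls also ended for RNVU1-25 without control replicate 2 (0.0652) or RNF26 replicate 1 (0.0744), for TEKTIP1 without RNF26 replicate 2 (0.0516) or 3 (0.0597), and for NEDD8-MDP1 without control replicate 1 (0.0737) or RNF26 replicate 2 (0.124) or 3 (0.0907). With no filter on low values RNVU1-25 (0.0640), TEKTIP1 (0.0669) and NEDD8-MDP1 (0.105) missed the threshold, and with a pseudocount of 0.1 TEKTIP1 (0.0587), NEDD8-MDP1 (0.0526) and CLPSL2 (0.0841). NEDD8-MDP1 (0.0771) also missed it with the replicate number as a block. Over all settings the adjusted p ranged over 0.00450 to 0.0588 for NMBR, 2.52e-04 to 0.0576 for RPL36A-HNRNPH2, 8.97e-04 to 0.0841 for CLPSL2, 0.0244 to 0.128 for NEDD8-MDP1, 7.86e-04 to 0.102 for RNVU1-25 and 0.00657 to 0.0790 for TEKTIP1.

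Wnt target genes fell in HCT15. The transcription factor gene SOX4 fell from 26.4 ± 3.21 to 11.4 ± 1.01 TPM, and ZNRF3, a ubiquitin ligase that removes Wnt receptors, from 12.01 ± 0.7504 to 4.34 ± 0.536 TPM (SD, n = 3 each). MYC fell from 130 ± 15.2 to 64.2 ± 2.43 TPM and the secreted Wnt inhibitor DKK1 from 28.1 ± 3.94 to 14.04 ± 0.853 TPM. The log2 fold changes of SOX4, ZNRF3, MYC and DKK1 were -1.14, -1.29, -1.001 and -0.95, with limma adjusted p of 3.83e-05, 3.91e-05, 4.33e-05 and 4.97e-05. AXIN2, named after its values were seen, fell by 0.71 (SE 0.105, limma adjusted p = 4.70e-04), from 35.7 to 21.4 TPM. Of 31 tested targets 22 fell and 9 did not pass, and 25 fell adjusted over the list alone. The median was -0.53 relative to all genes (camera adjusted p = 2.17e-05, and adjusted p = 0.556 with an estimated correlation). After the GC and length correction the median was -0.35, with 16 falls and 1 rise. Of 45 Wnt ligands, receptors and other components 24 fell, 26 adjusted over the list alone (median -0.18, camera adjusted p = 0.0164, and adjusted p = 0.606 with an estimated correlation). They included the co-receptor gene LRP5 (-1.21), the scaffold genes AXIN1 (-1.03) and DVL1 (-0.72), and BCL9 (-0.65), a cofactor of beta-catenin. The call on the components ended after the GC and length correction (adjusted p = 0.242) and without HCT15 control replicate 3 (0.0512; range 3.58e-04 to 0.242).

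**Figure D3:**
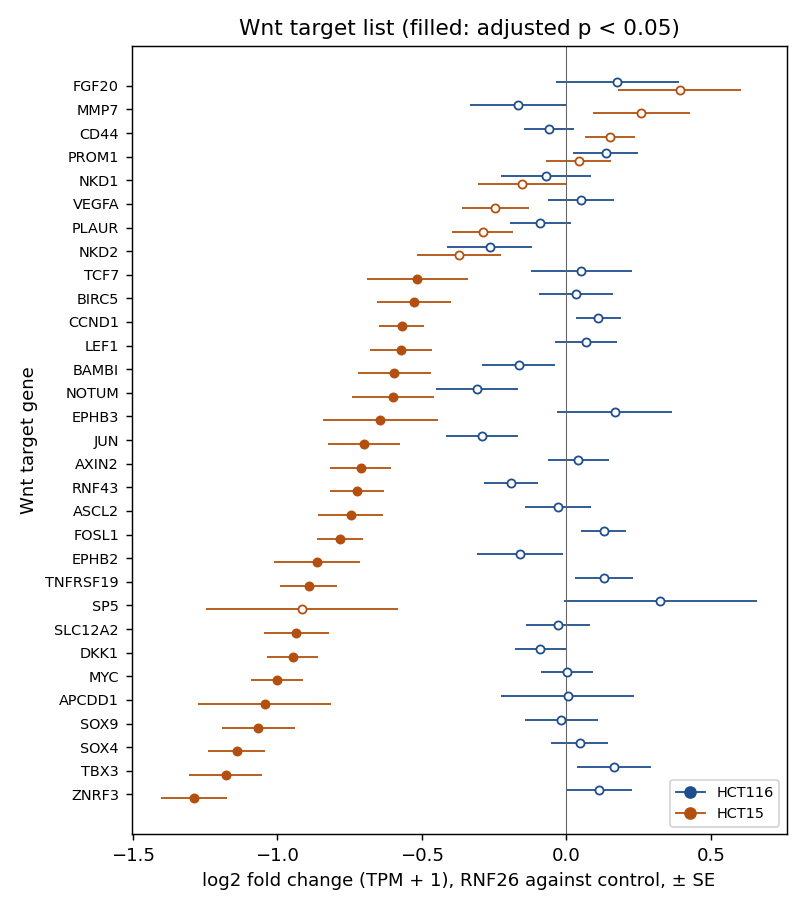
Log2 fold change (TPM + 1) ± SE of the 31 tested Wnt target genes, RNF26 against control, in HCT116 and HCT15; filled symbols mark limma adjusted p under 0.05. In HCT15 22 genes are lower and filled, and in HCT116 no symbol is filled.

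Genes of proliferation were mostly lower in HCT15. TYMS, the thymidylate synthase, fell from 200 ± 12.9 to 109 ± 5.51 TPM, and the replication helicase genes CDC45 and MCM2 from 38.3 ± 3.12 to 21.3 ± 1.07 and from 54.8 ± 1.08 to 27.3 ± 2.76 TPM (SD, n = 3 each). CCNE2, a cyclin of S phase entry, rose from 4.53 ± 0.166 to 8.94 ± 0.402 TPM (log2 fold change 0.84, limma adjusted p = 3.83e-05). Of 43 S phase genes 30 fell and 3 rose, 32 and 3 adjusted over the list alone (median -0.24 relative to all genes, camera adjusted p = 3.45e-04, and adjusted p = 0.606 with an estimated correlation). Of 44 G2/M genes 23 fell and 1 rose, 24 and 1 adjusted over the list alone (median -0.08, camera adjusted p = 0.0280, and adjusted p = 0.656 with an estimated correlation). Falls included the mitotic kinase genes PLK1 (-1.03) and AURKA (-0.40), the phosphatase gene CDC25B (-0.81) and the spindle gene TPX2 (-0.61). Of 39 MYC-responsive genes of ribosome biogenesis 24 fell, 30 fell and 1 rose adjusted over the list alone (median -0.15, camera adjusted p = 9.11e-04, and adjusted p = 0.594 with an estimated correlation), led by BOP1 (-1.18), RRP12 (-1.03), PPAN (-0.66) and RRP9 (-0.64). The G2/M call ended with median-ratio scaling (adjusted p = 0.494), quantile normalization (0.195), mitochondrial and ribosomal protein genes left out (0.171), a filter of 5 TPM (0.160), a fit of HCT15 alone (0.0584), the replicate number as a block (0.0637), and without HCT15 control replicate 3 (0.0663) or RNF26 replicate 3 (0.124, range 4.07e-07 to 0.494). That of ribosome biogenesis ended with median-ratio scaling (0.0646; range 3.03e-10 to 0.0646).

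Genes of cholesterol synthesis and uptake fell together in HCT15. DHCR7, which acts in the last steps of cholesterol synthesis, fell by 1.32 (log2, limma adjusted p = 2.30e-05), from 29.2 ± 1.48 to 11.1 ± 0.922 TPM (SD, n = 3 each). SREBF2, the transcription factor gene that controls the pathway, fell by 1.001 and the sterol sensor gene INSIG1 fell by 0.88. Of 28 tested 21 fell, 21 adjusted over the list alone (median -0.29 relative to all genes, camera adjusted p = 7.46e-06, and adjusted p = 0.556 with an estimated correlation). Of 29 fatty acid and lipid droplet genes 15 fell and 1 rose, 15 and 1 adjusted over the list alone (median -0.14, camera adjusted p = 0.0370, and adjusted p = 0.606 with an estimated correlation). Falls included SREBF1 (-1.10), the fatty acid synthase gene FASN (-1.48), from 17.5 ± 0.335 to 5.64 ± 0.456 TPM, the lipid droplet gene PLIN3 (-1.03) and ACLY (-0.99), which makes cytosolic acetyl-CoA. The fatty acid call ended with median-ratio scaling (adjusted p = 0.123), quantile normalization (0.0775), the GC and length correction (0.108), mitochondrial and ribosomal protein genes left out (0.0809), a filter of 5 TPM (0.126), a fit of HCT15 alone (0.0743), the replicate number as a block (0.0726) and without HCT15 RNF26 replicate 3 (0.0620, range 9.25e-06 to 0.126).

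Immediate early genes, which respond to growth factors and also to the handling of cells, and genes of amino acid stress, cell junctions and heat shock were lower in HCT15 too. Of 37 immediate early genes 29 fell, 29 adjusted over the list alone (median -0.35 relative to all genes, camera adjusted p = 1.67e-06, and adjusted p = 0.556 with an estimated correlation), among them PHLDA1 (-0.96), MYC, CCN2 (-1.15) and FOSL1 (-0.78). Of 37 ATF4 targets of the amino acid response 22 fell and 2 rose, 24 and 2 adjusted over the list alone (median -0.25, camera adjusted p = 0.00174, and adjusted p = 0.606 with an estimated correlation). They included SESN2 (-1.08), the amino acid transporter genes SLC7A5 (-1.07) and SLC7A1 (-0.98), and GDF15, which fell from 316 ± 32.0 to 147 ± 10.1 TPM (SD, n = 3 each). Of 36 epithelial junction and keratin genes 21 fell and 1 rose, 23 and 1 adjusted over the list alone (median -0.24, camera adjusted p = 0.00106, and adjusted p = 0.556 with an estimated correlation), with the membrane protease gene ST14 (-1.22), the desmosome genes PKP2 (-0.77) and JUP (-1.25), and LAD1 (-0.93) leading the falls. Of 22 YAP targets 14 fell and 2 rose, 15 and 2 adjusted over the list alone (median -0.36, camera adjusted p = 0.0164, and adjusted p = 0.594 with an estimated correlation). CCN2, AJUBA (-0.79) and DDAH1 (-0.60) fell and NT5E (0.68) rose. Of 20 heat shock genes 11 fell and 1 rose, 11 and 1 adjusted over the list alone (median -0.19, camera adjusted p = 0.0164, and adjusted p = 0.606 with an estimated correlation), among them the chaperone gene HSP90AA1, from 1155 ± 177 to 459 ± 26.4 TPM, HSPB1, DNAJB1 (-0.56) and BAG3 (-0.99). The heat shock call ended with median-ratio scaling (adjusted p = 0.149), mitochondrial and ribosomal protein genes left out (0.0576) and a filter of 5 TPM (0.0850; range 1.39e-04 to 0.149), and the YAP call with that filter (0.140; range 2.46e-05 to 0.140).

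Genes beside RNF26 on chromosome 11 were lower in HCT15 as well. The histone variant gene H2AX fell from 52.9 ± 3.18 to 28.8 ± 3.37 TPM (SD, n = 3 each), and DPAGT1 (-0.39) and HINFP (-0.42) fell too. Of 10 tested 7 fell, 7 adjusted over the list alone (median -0.24 relative to all genes, camera adjusted p = 0.0315, and adjusted p = 0.556 with an estimated correlation). The call ended with a filter of 5 TPM (adjusted p = 0.0883), in a fit of HCT15 alone (0.0584), after the GC and length correction (0.1503) and without HCT15 control replicate 3 (0.0539, range 0.00763 to 0.1503). Over all tested genes 4857 of 15584 fell. A wider stretch of 141 neighbouring tested genes that spans RNF26 had a median log2 fold change of -0.00686 in HCT15 after that correction. A fall of the whole region was therefore not seen.

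The number of falls within several of these lists moved with the scaling. With median-ratio scaling 12 G2/M genes fell and 8 rose, and 11 genes of ribosome biogenesis fell and 2 rose, 6 heat shock genes fell and 2 rose, and 19 immediate early genes and 4 genes beside RNF26 fell. With quantile normalization 9 fatty acid genes fell and 4 rose, 15 Wnt components fell and 1 rose, and 14 genes of ribosome biogenesis fell and 1 rose. In a fit of HCT15 alone 15 G2/M genes and 15 genes of ribosome biogenesis fell. After the GC and length correction 16 immediate early genes fell and 2 rose, 13 epithelial genes fell and 5 rose, 9 Wnt components fell and 3 rose, and 13 genes of ribosome biogenesis and 3 genes beside RNF26 fell. List medians relative to all genes were -0.03 for G2/M and -0.10 for ribosome biogenesis with median-ratio scaling, and -0.05 for G2/M, -0.09 for fatty acid genes and -0.12 for Wnt components with quantile normalization. After the GC and length correction they were -0.21 for G2/M, -0.14 for epithelial genes and -0.15 for genes beside RNF26, and with no filter -0.25 for G2/M, -0.40 for S phase, -0.40 for epithelial, -0.30 for fatty acid, -0.33 for heat shock and -0.31 for ribosome biogenesis genes.

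Lists tied to invasion were not called in HCT15. Of 22 mesenchymal genes 5 fell and 1 rose; adjusted over the list alone 3 fell. The falls included CCN2, CCN1 (-0.92) and THBS1 (-0.52). The list's median lay 0.02 above that of all genes while its mean difference was -0.08 (camera adjusted p = 0.676, and adjusted p = 0.798 with an estimated correlation). Of 31 extracellular protease and motility genes 12 fell and 1 rose, 13 and 2 adjusted over the list alone (median -0.11, camera adjusted p = 0.343, and adjusted p = 0.763 with an estimated correlation), and the list was called with no filter on low values (adjusted p = 0.0481, range over the settings with the preset correlation 0.0481 to 0.691). PLAU, the urokinase gene, fell from 17.2 ± 0.458 to 9.31 ± 0.0231 TPM (SD, n = 3 each), and CTSD (-0.89), RHOB (-0.64) and PLAT (-0.89) fell too.

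Ribosomal protein mRNAs rose in HCT15. RPS23 rose from 4501 ± 206 to 6435 ± 319 TPM, RPL35A from 1029.6 ± 257 to 1943 ± 161 TPM, RPL37 from 2548 ± 118 to 3461 ± 61.9 TPM and RPS27 from 6078 ± 622 to 9014 ± 414 TPM (SD, n = 3 each). Of 77 tested 47 rose and 30 did not pass, and 52 rose adjusted over the list alone (median 0.56 relative to all genes, camera adjusted p = 1.55e-27, and adjusted p = 0.556 with an estimated correlation). Reads of these genes can be shared with their pseudogenes. The genes took 20.3% ± 3.26 of TPM in control and 25.7% ± 0.590 in RNF26 libraries of HCT15 (SD, n = 3 each), and 21.2% and 20.9% in the HCT116 arms. HCT15 control replicate 3 stood apart, with 16.8% ribosomal protein and 25.9% mitochondrial TPM, against 20.8% and 23.2% ribosomal protein and 17.7% and 16.4% mitochondrial TPM in the other controls. Without it 37 ribosomal protein genes rose and 1 fell (median 0.43), and with quantile normalization 24 rose and 3 fell (median 0.19). Rises were 30 without HCT15 RNF26 replicate 1, 30 with no filter and 9 in a fit of HCT15 alone. Of 58 nuclear genes of oxidative phosphorylation 17 rose and 9 fell, 17 and 9 adjusted over the list alone (median 0.34, camera adjusted p = 3.51e-05, and adjusted p = 0.656 with an estimated correlation). The respiratory chain genes UQCRC1 (-0.93), SDHA (-0.73) and NDUFV1 (-0.64) fell and the ATP synthase gene ATP5F1E (0.90) rose. With median-ratio scaling 32 genes of this list rose and 6 fell, with mitochondrial and ribosomal protein genes left out 28 rose and 8 fell, in a fit of HCT15 alone 3 rose and 7 fell, and with no filter 7 rose and 9 fell. Rises and falls were 11 and 8 without HCT15 control replicate 1, 30 and 9 without 2 and 11 and 11 without 3 (median 0.21, camera adjusted p = 0.0302), and 6 and 8 without RNF26 replicate 1, 10 and 10 without 2 and 10 and 9 without 3.

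**Figure D4:**
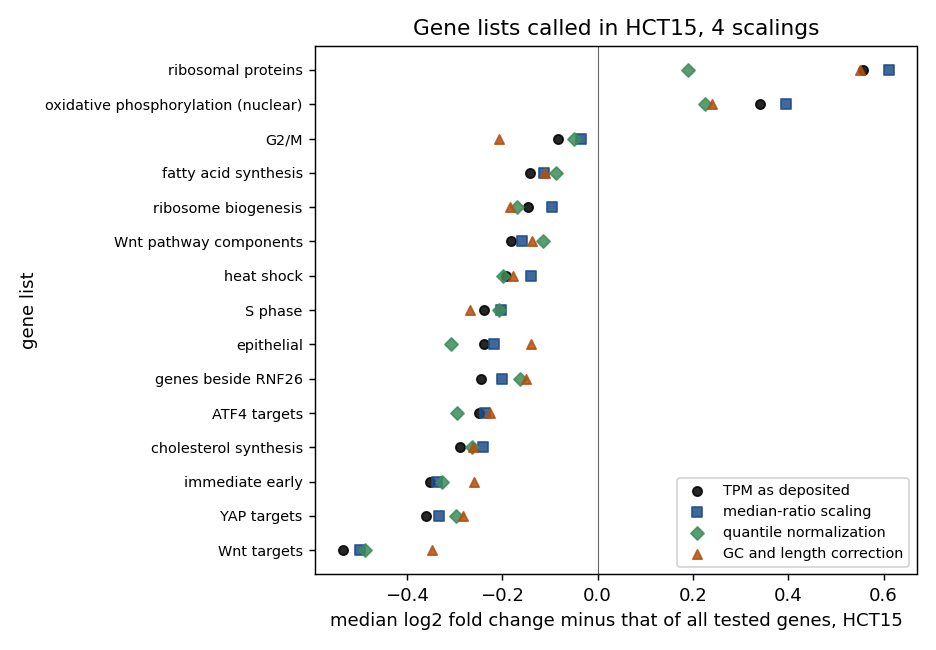
Median log2 fold change, RNF26 against control, of each of the 15 gene lists called in HCT15, minus the median of all tested genes, for TPM as deposited and under other scalings or corrections. Ribosomal protein and oxidative phosphorylation genes lie above 0 and the other 13 lists below 0 in each setting drawn.

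The RNF26 effect differed between the lines for 3190 genes (limma interaction, adjusted p under 0.05), 281 higher and 2909 lower in HCT15 than in HCT116. After RNF26, CARM1, an arginine methyltransferase gene, had the smallest p, with a difference of the log2 effects of -1.12 (HCT15 minus HCT116, SE 0.0864, adjusted p = 3.59e-04). It went from 31.4 ± 0.656 to 32.1 ± 2.20 TPM in HCT116 and from 59.3 ± 1.39 to 27.2 ± 0.718 TPM in HCT15 (SD, n = 3 each). SERPINE2, a secreted protease inhibitor gene, rose in HCT15 from 9.48 ± 0.699 to 24.4 ± 1.51 TPM and averaged 29.4 and 26.5 TPM in the HCT116 arms (difference 1.42, adjusted p = 3.90e-04). Negative differences of the log2 effects were found for DHCR7 (-1.40), CCAR2 (-1.23), the beta-tubulin gene TUBB2A (-0.99), the endoplasmic reticulum gene CRELD2 (-1.20), NACC1 (-1.03) and SREBF1 (-1.20). Of 31 Wnt targets 17 were lower by this test, 19 adjusted over the list alone (median -0.49 relative to all genes, camera adjusted p = 3.43e-05, and adjusted p = 0.383 with an estimated correlation). The number of lower targets was 11 with median-ratio scaling, 11 with quantile normalization and 10 after the GC and length correction. The split was 934 higher and 1146 lower with median-ratio scaling, 856 higher and 1076 lower with quantile normalization, 513 higher and 1836 lower with mitochondrial and ribosomal protein genes left out, and 629 higher and 1013 lower after the GC and length correction. The count was 2089 without HCT116 control replicate 3, 2125 without HCT116 RNF26 replicate 1 and 1941 without HCT116 RNF26 replicate 2. Positive differences were 636 without HCT15 control replicate 2, 166 and 137 without HCT116 control replicate 1 or 3, and 168 and 132 without HCT116 RNF26 replicate 1 or 2.

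The mean effect over both lines was called for 3305 genes (limma, adjusted p under 0.05), 411 higher and 2894 lower. With the same sign in both lines, rises were led by RNF26 (mean log2 fold change 2.52), CCNE2 (0.47), the readthrough locus RPL17-C18orf32 (0.61), the organic anion transporter gene SLCO1B3 (0.59) and NIBAN1 (0.80). Falls were led by BCKDK (-0.66), a kinase of branched-chain amino acid breakdown, the peptidase gene APEH (-0.66), TUBA1B (-0.57), the transcription factor gene ETS2 (-0.53) and TUBB2A (-0.49). In HCT116 alone the log2 fold change of TUBB2A was -1.93e-04, and CCNE2, RPL17-C18orf32, SLCO1B3 and NIBAN1 had 0.09, 0.12, 0.17 and 0.06. There BCKDK, APEH, TUBA1B and ETS2 had log2 fold changes of -0.21, -0.20, -0.13 and -0.03. None of these passed in HCT116, and in HCT15 BCKDK, APEH, TUBA1B and ETS2 fell, with -1.12, -1.13, -1.02 and -1.03. Of 31 Wnt targets 20 were lower, 22 adjusted over the list alone (median -0.25 relative to all genes, camera adjusted p = 1.09e-05, and adjusted p = 0.487 with an estimated correlation). After the GC and length correction 10 were lower, with a median of -0.17 relative to all genes. The split of genes was 1197 higher and 1505 lower with median-ratio scaling, 1174 higher and 1446 lower with quantile normalization, 723 higher and 1927 lower with mitochondrial and ribosomal protein genes left out, and 594 higher and 1096 lower after the GC and length correction. Rises were 749 without HCT15 control replicate 2, 241 and 246 without HCT116 control replicate 1 or 2, 237 without HCT116 RNF26 replicate 1 and 266 with no filter.

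RNF26 was the single gene called in both lines with the same sign, where 0.0539 shared rises are expected by chance (one-sided Fisher exact test, p = 0.0539). RNF26 was also the single gene called in HCT116 and was overexpressed in both lines by design. The overlap and its p therefore say nothing about a shared response. Across the 15583 genes other than RNF26, the fold changes of the lines had a Pearson r of 0.0173 and a Spearman rho of 0.0641. Across the 5696 of them called in HCT15 these were 0.102 and 0.0927, and 52.8% had the same sign in both lines. These correlations are across genes, which are not independent replicates.

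The control libraries describe how far apart the lines were without RNF26. LCN2 averaged 349 ± 41.0 TPM in HCT15 and 0.693 ± 0.429 TPM in HCT116, and the cytokine gene LTB 131 ± 17.6 and 0.0733 ± 0.102 TPM (SD, n = 3 each). OLR1, a scavenger receptor gene, and CBR1, a carbonyl reductase gene, averaged 300.1 and 181 TPM in HCT15 and were listed at 0 in the HCT116 controls, and the glutathione transferase gene GSTM3 averaged 124 and 0.0133 TPM in the lines. Higher in HCT116 were GTSF1 (292 TPM), ADIRF (474 TPM) and MAGEB2 (138 TPM), with HCT15 means of 0.123, 1.32 and 0.0133 TPM. The small RNA gene RNY1 averaged 168 ± 87.8 TPM in the HCT116 controls, a wide spread, and was listed at 0 in HCT15. In the HCT116 RNF26 libraries RNY1 averaged 374 ± 111 TPM (SD, n = 3 each), and limma did not call the change. In all, 10836 of 15584 genes differed (limma, adjusted p under 0.05), 6790 higher and 4046 lower in HCT15, and the split was 5473 higher and 5243 lower with quantile normalization and 5395 higher and 5094 lower after the GC and length correction. List tests of this comparison were added after the data were examined. NF-kB targets and cytokines were higher in HCT15 for 27 of 31 genes, 27 adjusted over the list alone (camera adjusted p = 3.38e-08, and adjusted p = 0.145 with an estimated correlation), and ATF4 targets for 34 of 37, 34 adjusted over the list alone (camera adjusted p = 5.27e-10, and adjusted p = 0.254 with an estimated correlation). Heat shock genes were lower in HCT15 for 17 of 20, 17 adjusted over the list alone (camera adjusted p = 1.31e-08, and adjusted p = 0.254 with an estimated correlation), and proteasome genes for 28 of 31, 29 adjusted over the list alone (camera adjusted p = 1.31e-08, and adjusted p = 0.254 with an estimated correlation). Wnt targets were higher in HCT15 for 21 of 31 genes and lower for 5, the same adjusted over the list alone (camera adjusted p = 0.0889, and adjusted p = 0.605 with an estimated correlation).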

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

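The tests of a shared response and of median-ratio scaling were chosen after the result was seen, as were the GC and length correction and the removal of mitochondrial and ribosomal protein genes as settings. The RNF26 effect differed between the lines by the limma interaction test for 3190 genes, and the differences below (HCT15 minus HCT116, log2) passed that test. They were -3.07 for RNF26 and 3.87 for CTNNA2, which is listed at 0 in HCT15 controls and spreads widely in HCT15 RNF26 libraries. Next came 2.74 for NMBR, 2.55 for RPL36A-HNRNPH2, 1.96 for SAA1, 1.70 for CLPSL2, 1.48 for NIBAN1, 1.42 for SERPINE2 and 1.40 for LCN2. Further positive differences were 0.98 for RPL17-C18orf32, 0.82 for SLCO1B3 and 0.75 for CCNE2. Negative ones were -1.98 for MAP3K9, -1.79 for HSPB1, -1.60 for DUSP8, -1.54 for VIL1, -1.49 for AKAP12, -1.40 for DHCR7, -1.35 for MYADM, -1.34 for H19, -1.25 for NR1D1, -1.23 for CCAR2, -1.20 for CRELD2, -1.20 for SREBF1, -1.12 for CARM1 and -1.03 for NACC1. Smaller ones were -0.997 for ETS2, -0.99 for TUBB2A, -0.93 for APEH, -0.91 for BCKDK and -0.89 for TUBA1B. The differences of MAP3K9 (SE 0.638, limma adjusted p = 0.0496) and RPL36A-HNRNPH2 (SE 0.806, limma adjusted p = 0.0455) lay close to the threshold.

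Of 36 gene lists 16 differed between the lines by camera with its preset correlation, and with an estimated correlation camera called 0. Relative to all genes the median difference of the effects (log2) was 0.59 for ribosomal protein genes, 0.36 for nuclear genes of oxidative phosphorylation, 0.30 for interferon-stimulated genes, 0.23 for mitochondrial mRNAs and 0.10 for NF-kB targets. It was -0.49 for Wnt targets, -0.37 for YAP targets, -0.30 for immediate early genes, -0.27 for S phase, -0.26 for cholesterol, -0.21 for epithelial, -0.20 for ATF4, -0.19 for Wnt component, -0.17 for ribosome biogenesis, -0.14 for heat shock and -0.12 for G2/M genes.

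Limma called 5697 genes in HCT15 and 1 in HCT116, although RNF26 mRNA rose more in HCT116. The tables argue against a response to the RNF26 level that both lines share, since the genes called in HCT15 other than RNF26 had a median signed log2 fold change of 0.53 there and of 1.46% of that in HCT116. They also argue against a trend in GC content and transcript length as the whole cause, since after its removal 4173 genes were called, 74.5% of the count over the same genes, and 3038 of them were among the 5604 called before, though the rises over these genes went from 808 to 1767. The tables argue against a single deviating library too. Without any 1 HCT15 library the count was at least 77.0% of that with all. In the lowest case 4270 of the 5697 genes were called again. A difference in culture, handling or library preparation between the HCT15 arms may have given the same pattern and cannot be told apart from RNF26, since 0 libraries carry a batch label while immediate early genes, which also read handling, were lower in HCT15 (median -0.35 relative to all genes), and a response to RNF26 in HCT15 alone stays open too.

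Falls made up 85.3% of the HCT15 calls. With median-ratio scaling the share was 53.7%, but this scaling centres the fold changes, with a median of 0 over all genes, so the share decides nothing and a shift in the scale of whole libraries stays open. With mitochondrial and ribosomal protein genes left out it was 71.5%, between the bounds set for that test, so the share that these abundant mRNAs could account for stays open. The HCT15 median log2 fold change was -0.00519 in genes with a median GC content of 40.9% and -0.408 in those with 61.1%. After the GC and length correction falls made up 57.7% of the calls. This correction also centres the fold changes, with a median of -0.0121, so that share decides nothing either. A GC trend as the cause of part of the falls stays open. TPM values cannot tell a fall of most mRNAs from a change of scale, and no biological explanation was tested.

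Ribosomal protein mRNAs were higher in HCT15 with RNF26. For their short transcripts and GC content, 98.9% of the list's median fold change, relative to all genes, was left after the correction. This argues against a trend with the GC content and length used there. Both were medians over all annotated transcripts of a gene, which may differ from those expressed. A bias tied to the short expressed mRNAs themselves therefore stays open. For reads moved from pseudogenes, the log2 change of the sum of genes and pseudogenes was 101% of that of the genes. That share decides nothing, since pseudogenes held 9549 ± 1598 TPM in HCT15 controls and the genes 202690 ± 32578 TPM (SD). The pseudogene sum itself rose to 12445 ± 267 TPM with RNF26 (log2 change 0.396), where a move of reads to the genes would lower it. These sums argue against such a move as the cause. Whether RNF26 or a difference in handling between the arms raised the ribosomal protein mRNAs stays open, as for the other HCT15 calls.

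For HCT116, 8 of the 10 splits of the 6 libraries into 3 and 3 called at least 1 gene, and the highest other called 7. For HCT15 1 of 10 called 5697, the real one, and the highest other called 6. For the control lines 1 of 10 called 10836, the real one, and limma called 0 in the highest other. With 3 against 3 the splits are too few for a share under 0.05. For the mean effect 5 of 100 drawn splits within lines called as many as the real 3305 (highest other 4167), and for the difference 7 of 100 called as many as the real 3190 (highest other 4167), so chance is not excluded for either. All of these were among the 12 splits that kept the HCT15 arms whole, which called 2246 genes or more, while splits that mixed the HCT15 arms called at most 9.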

How the results depend on the processing

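The GC and length correction and the removal of mitochondrial and ribosomal protein genes were chosen after the result was seen. Sequencing depth limits low values, and TPM does not show it. No called effect of a named gene, and no called list of HCT116 or HCT15, turned its direction under the settings run. For the difference between lines the NF-kB list ran up by camera and down by fry (adjusted p = 0.754), and the list of mitochondrial mRNAs turned with quantile normalization. Among all genes called both with and without a setting, 3036 of 3038 in HCT15 had the same sign after the GC and length correction and 9395 of 9396 in the control lines with quantile normalization, and under each other setting all had. With a log2 fold change of 1 or more required, limma called 302 genes in HCT15, 312 for the difference, 19 for the mean effect and 4315 for the control lines, by construction. Without HCT15 control replicate 2 these counts were 520 in HCT15, 580 for the difference and 41 for the mean, and the difference gave 204 without HCT116 RNF26 replicate 2. A pseudocount of 0.1 gave 630, 558 and 51, and 5543 for the control lines, a pseudocount of 5 gave 81, 79, 5 and 1881, and after the GC and length correction it was 121 in HCT15 and 102 for the difference. Median-ratio scaling gave 188 in HCT15 and 151 for the difference, quantile normalization 200 and 151, and for the mean it was 10 with no filter and 12 with robust estimation. With an estimated correlation camera called 0 lists in HCT116, HCT15, the difference and the mean, and the Wnt target list had an adjusted p of 0.556 in HCT15, 0.383 for the difference and 0.487 for the mean. Fry, which does not compare a list with other genes, called 0 lists in HCT116, 29 in HCT15, 27 for the difference and 28 for the mean. In HCT116 limma called 11 genes with no filter and 3 in a fit of that line alone, where camera called 8 lists; after the GC and length correction it called 2 lists. The count for the difference was 2080 with median-ratio scaling, 1932 with quantile normalization and 1642 after the GC and length correction, and that for the mean effect was 1690 after this correction. For these changes the cause was not tested.

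With 1 library left out, genes called ranged from 1 to 3 in HCT116, 4384 to 5878 in HCT15, 1941 to 3857 for the difference, 2357 to 3858 for the mean and 10136 to 10859 for the control lines. Lists called ranged from 1 to 5 in HCT116, 13 to 17 in HCT15, 14 to 17 for the difference and 13 to 16 for the mean. In HCT116 2 lists were called without control replicate 1 and 1 without RNF26 replicate 3. The adjusted p of the Wnt target list ranged from 6.93e-06 to 7.43e-05 in HCT15, 1.30e-05 to 1.88e-04 for the difference and 1.72e-06 to 3.75e-05 for the mean. The log2 fold change of RNF26 ranged from 3.96 to 4.15 in HCT116 and 0.96 to 1.002 in HCT15, and the correlation of the lines' fold changes from -0.0242 to 0.0693. Where an arm was left with 2 libraries, the shared spread of the fit was used. Of 50 called effects of named genes, 586 of 600 values with a library left out, 441 of 457 under other settings chosen before and 99 of 100 under added ones stayed past the threshold. Of 18 called lists of HCT116 and HCT15 other than the Wnt targets, the values for camera with its preset correlation were 200 of 216, 164 of 180 and 27 of 35, with 0 of 18 staying past it with an estimated correlation and 13 of 18 by fry.

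Replicate numbers did not pair the libraries in HCT116, or in HCT15 apart from replicate 3. Deviations of same-numbered control and RNF26 libraries correlated at -0.0313, -0.0424 and -0.0254 in HCT116 and 0.00895, 0.0135 and 0.146 in HCT15. The libraries of HCT15 replicate 3 correlated best with each other, and every other library with a different number. With the replicate number as a block limma called 2 genes in HCT116, 5116 in HCT15, 2306 for the difference and 2552 for the mean, and the G2/M (adjusted p = 0.0637) and fatty acid (0.0726) lists and NEDD8-MDP1 (0.0771) missed the threshold in HCT15. The block gives no value for the control lines, and separate fits give none for the difference, the mean or the control lines.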

Other observations

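The test of a chromosome segment was planned before its result was seen, and the GC and length correction was chosen after the data were seen. Gene groups of HCT15 not described above follow, some with calls in both directions and some in a single direction (RNF26 against control, limma). Medians are relative to all genes (log2). Among NF-kB targets and cytokines, of 31 tested 8 fell and 8 rose, 9 and 9 adjusted over the list alone (median 0.03, mean 0.22, camera adjusted p = 0.0838, and adjusted p = 0.606 with an estimated correlation): SAA1 (1.85) and LCN2 (1.43) rose and ICAM1 (-0.93), an adhesion molecule, and NFKB1 (-0.79) fell. That list was called without HCT15 control replicate 1 (adjusted p = 0.0437) and with a filter of 5 TPM (0.0189, range 0.0189 to 0.506). Among interferon-stimulated genes, of 32 tested 5 fell and 2 rose, 5 and 2 adjusted over the list alone (median 0.18, camera adjusted p = 0.123, and adjusted p = 0.594 with an estimated correlation): IFI27 rose (1.503) and LGALS3BP (-0.88), OAS3 (-0.67) and IRF7 (-0.74) fell. Of antigen presentation genes, of 23 tested 5 fell and 2 rose, 5 and 2 adjusted over the list alone (median 0.16, camera adjusted p = 0.483, and adjusted p = 0.763 with an estimated correlation), and B2M (0.37) rose while CALR (-1.06), TAPBP (-0.79) and PDIA3 (-0.42) fell. After the GC and length correction both lists were called (adjusted p = 0.0442 each, range 0.0442 to 0.536 for interferon and 0.0442 to 0.988 for antigen presentation). Of cGAS-STING genes, of 13 tested 6 fell, 6 adjusted over the list alone (median -0.12, camera adjusted p = 0.343, and adjusted p = 0.656 with an estimated correlation), among them IKBKE (-0.64), STING1 (-0.50), IRF3 (-0.53) and TRIM32 (-0.40). Of partners of RNF26 in vesicle positioning, of 21 tested 8 fell, 8 adjusted over the list alone (median 0.05, while camera ran down, camera adjusted p = 0.708, and adjusted p = 0.865 with an estimated correlation), among them TMEM43 (-0.64), LAMP1 (-0.57), EGFR (-0.66) and TOLLIP (-0.47). The direction of that test turned up with median-ratio scaling, quantile normalization and mitochondrial and ribosomal protein genes left out.

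Of unfolded protein response genes, of 33 tested 13 fell and 5 rose, 14 and 5 adjusted over the list alone (median 0.02, camera adjusted p = 0.708, and adjusted p = 0.865 with an estimated correlation), with falls of CRELD2 (-1.21), PDIA4 (-1.05), CALR (-1.06) and PDIA6 (-0.48). Of hypoxia and glycolysis genes, of 40 tested 16 fell and 1 rose, 16 and 1 adjusted over the list alone (median -0.13, camera adjusted p = 0.0838, and adjusted p = 0.656 with an estimated correlation), with falls of the pyruvate kinase gene PKM (-1.12), PFKP (-0.74), HK1 (-0.96) and the glucose transporter gene SLC2A1 (-1.08). That list was called with no filter (adjusted p = 4.16e-05), with quantile normalization (0.0385) and without HCT15 control replicate 3 (0.0302, range 4.16e-05 to 0.476). Of p53 targets, of 33 tested 14 fell and 2 rose, 15 and 3 adjusted over the list alone (median -0.03, camera adjusted p = 0.308, and adjusted p = 0.751 with an estimated correlation), with falls of SESN2 (-1.08), CDKN1A (-0.75), GDF15 (-1.10) and AEN (-0.59), and of NRF2 targets, of 25 tested 11 fell, 11 adjusted over the list alone (median -0.01, camera adjusted p = 0.392, and adjusted p = 0.763 with an estimated correlation), with falls of TKT (-0.53), PGD (-0.53) and EPHX1 (-0.73). Of autophagy and lysosome genes, of 42 tested 20 fell and 3 rose, 20 and 3 adjusted over the list alone (median -0.04, camera adjusted p = 0.261, and adjusted p = 0.766 with an estimated correlation), with falls of ATP6AP1 (-0.95), CTSD (-0.89) and TFE3 (-0.74). Of proteasome subunit genes, of 31 tested 13 fell and 2 rose, 14 and 3 adjusted over the list alone (median 0.07, while camera ran down, camera adjusted p = 0.708, and adjusted p = 0.865 with an estimated correlation), with falls of PSMD2 (-0.93), PSMD3 (-0.76), PSMD1 (-0.56) and PSMD8 (-0.57), and the direction of that test turned up with median-ratio scaling and with mitochondrial and ribosomal protein genes left out. Of transporter and xenobiotic genes, of 19 tested 9 fell, 9 adjusted over the list alone (median -0.08, camera adjusted p = 0.312, and adjusted p = 0.656 with an estimated correlation), led by CYP2S1 (-0.97), ABCB1 (-1.21), ABCC5 (-0.69) and ABCC1 (-0.95). With no filter on low values the lists of p53 targets (adjusted p = 0.00195, range 0.00195 to 0.471), NRF2 targets (0.0115, range 0.0115 to 0.861), autophagy (3.58e-04, range 3.58e-04 to 0.834), proteasome (0.0284, range 0.0284 to 0.944) and transporter genes (0.00528, range 0.00528 to 0.711) were called as lower.

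Of TGF-beta and BMP response genes, of 20 tested 11 fell and 1 rose, 11 and 1 adjusted over the list alone (median -0.22, camera adjusted p = 0.194, and adjusted p = 0.656 with an estimated correlation), with falls of BMP4 (-0.78), TGIF1 (-0.56) and LTBP3 (-0.54). Of colon identity genes, of 9 tested 5 fell and 2 rose, 5 and 3 adjusted over the list alone (median -0.37, camera adjusted p = 0.708, and adjusted p = 0.798 with an estimated correlation), with falls of VIL1 (-1.59) and of the transcription factor genes HNF4A (-0.84) and CDX2 (-1.37). Of mitochondrially encoded mRNAs, of 13 tested 2 rose, 2 adjusted over the list alone (median 0.16, camera adjusted p = 0.0749, and adjusted p = 0.751 with an estimated correlation), MT-ND3 (0.46) and MT-CO3 (0.33). Camera called these mRNAs higher without HCT15 control replicate 3 (adjusted p = 1.52e-05) or RNF26 replicate 2 (0.0197) and with a filter of 5 TPM (0.0442, range 1.52e-05 to 0.725), and its direction turned with quantile normalization. Of replication-dependent histone genes, whose mRNAs mostly lack poly(A) tails, of 33 tested 1 fell and 2 rose, 1 and 1 adjusted over the list alone (median -0.04, while camera ran up, camera adjusted p = 0.308, and adjusted p = 0.751 with an estimated correlation); H2BC5 (0.73) and H3C10 (0.63) rose and H2AC17 (-0.98) fell, and camera called the list without HCT15 RNF26 replicate 2 (adjusted p = 0.0270, range 0.0270 to 0.988). With median-ratio scaling or quantile normalization the direction of the histone test turned down. Markers of cells that the cultures should not hold were few. The stromal gene PCOLCE (-0.82, 1 of 3 fibroblast markers, 1 adjusted over the list alone, camera adjusted p = 0.832, and adjusted p = 0.894 with an estimated correlation), the leukocyte gene CD14 (-0.47, 1 of 3, 1 adjusted over the list alone, camera adjusted p = 0.708, and adjusted p = 0.856 with an estimated correlation) and the endothelial gene ESAM (-0.62, the single one tested, 1 adjusted over the list alone) fell. Of 3 red cell and platelet markers limma called 0, with 0 at an unadjusted p under 0.05 (median 0.17, mean -0.00617, camera adjusted p = 0.676, and adjusted p = 0.763 with an estimated correlation), and of 2 neuroendocrine markers SCG5 (0.59) was called adjusted over the list alone. The direction of the test of red cell and platelet markers turned with median-ratio scaling and quantile normalization, and those of fibroblast and immune markers turned with the GC and length correction.

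A gained or lost chromosome segment in 1 of the HCT15 arms may move its genes together. In bins of at least 100 neighbouring tested genes the median log2 fold change of HCT15, corrected for GC content and length, lay farthest from 0 at -0.169, on chromosome 14 from 72926332 to 92839963 of GRCh38. Medians of the 137 bins ranged up to 0.117 in HCT15 and from -0.0396 to 0.0371 in HCT116, while between the control lines 10 bins lay beyond 0.3 either way. The value lies between the bounds set before the test, so a gain or loss in part of the cells stays open.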
